A study of Drosophila melanogaster with 3 samples.

How the data were processed

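Binding of Ultraspiracle (USP) was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole wandering larvae of the third instar, males and females together, of a Drosophila melanogaster strain that stably expressed usp with eGFP at its C terminus. USP is the fly relative of the vertebrate RXR receptors and the partner of EcR in the ecdysone receptor. The antibody was directed against GFP, and chromatin was sheared by sonication to 200 to 800 bp, per the labels. The labels gave 3 biological replicates of 1 group, numbered 1 to 3, each with a biological sample of its own. The study holds no second group, so the comparisons were between replicates, between bound and unbound parts of the genome, and between strong and weak peaks.

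The authors deposited 1 list of peaks per replicate, 1 list called on pooled data and 1 list labelled as optimal IDR-thresholded peaks. IDR is the irreproducible discovery rate, a measure of reproducibility. Per the file headers, alignments to genome build dm6 and a control alignment went into each call. Per the same headers, the pooled list and the IDR-thresholded list were derived from replicates 2 and 3, and replicate 1 was not among their parents. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal in the deposited lists is the caller's score of each peak, as the narrowPeak format defines it, and was not scaled between libraries. It was used only to rank peaks and to describe them within a list. The −log10 q-value that the authors deposited reached the same maximum in all IDR-thresholded peaks and was not used to rank them. The summit of each peak is an offset from the start of its interval, per the narrowPeak layout of the deposited lists.

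Each replicate's list and the pooled list held exactly 30000 rows, a cap seen in the values, so the lengths of these lists carry no information. The IDR-thresholded list held 11195 peaks, which were the 11195 peaks of highest signal in the pooled list. Membership thus equalled a cut by pooled signal. The lists do not show that each peak by itself was reproducible between replicates. A peak interval could hold several summits: the 11195 summits lay in 8915 different intervals. The number of reads per library is unknown from these files, and no interval that needs it is given. Each replicate was therefore cut to its 11195 peaks of highest signal before replicates were compared. The share of summits at exactly the same base in 2 replicates lay between 1.34% and 1.86% of 30000, so no library had been deposited more than once. All peaks lay on 2L, 2R, 3L, 3R, 4 and X.

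Gene models came from Ensembl release 115 (assembly BDGP6.54), and sequence came from the RefSeq copy of release 6 of the genome, whose coordinates are those of dm6. All peaks lay inside the chromosome lengths, and 30540 of 30593 annotated start codons (99.8%) read ATG at their annotated positions. Transposable elements and unnamed entries such as those of mature microRNAs were left out, which left 17683 genes with 23133 transcription start sites (TSSs), 13945 of the genes being protein-coding. Coordinates are 1-based on dm6. Of the symbols in the gene lists, 7 had been replaced in this annotation and were found through the synonyms of the RefSeq gene table, a step taken after first results had been seen. They were phm (now phtm), Tor (mTor), dbt (dco), Eip71CD (MsrA), Eip55E (Cth), Mst35Ba (ProtA) and Mst35Bb (ProtB).

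Agreement between replicates was the share of summits of a replicate with a summit of another within 100 bp, over the ordered pairs, tested one-sided against 1000 circular rotations (circular permutations) of a list along each chromosome arm. Summits were placed in classes in this order of priority: promoter (within 500 bp of a TSS), 5′ UTR, CDS, 3′ UTR, noncoding exon, intron, intergenic. The share of each class was tested two-sided against 1000 rotations, with Benjamini-Hochberg adjustment over the classes. A gene was called bound when a summit lay in its body or up to 1000 bp upstream. For each of 21 gene lists the number of bound genes was compared, two-sided, with 100000 random lists of protein-coding genes drawn without replacement within 20 bins of length, a permutation test, with Benjamini-Hochberg adjustment over the lists. Genes that overlap share their summits, and neighbours within a gene cluster are not independent in this test. The random lists were matched on length alone. They were not matched on expression or on the activity of promoters, so a list can differ from them through these as well.

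For 20 sequence motifs, written as consensus sequences, the share of summits with a match on either strand within 100 bp was compared with that in windows shifted by 1000 bp to a random side, by an exact two-sided McNemar test with Benjamini-Hochberg adjustment. Up to 20 random orders of the letters of each consensus gave a control for base composition. Shifted windows can fall on a neighbouring summit, which lowers the contrast. They were not matched to the summits for class of sequence, so a motif of promoters or of coding sequence can also differ through position alone. The 2080 strand-collapsed 6-mers were tested in the same windows. Signal ranks were compared by permutation tests with 100000 resamples, and the density of peaks on X by an exact binomial test. These tests, like the McNemar test, treat peaks as independent. Several summits can share an interval or a gene, so their p-values can be too small. The p-values of these tests speak of peaks or genes within the IDR-thresholded list. The spread between cultures of larvae is given separately, as the SD over the 3 replicates' own lists, each cut to 11195 peaks. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only.

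The groups, gene lists, motifs, tests and most alternatives were fixed before the data were examined. Genes were named by a fixed rule: all members of the list of ecdysone response regulators, the genes at the 15 peaks of highest signal, the 10 protein-coding genes with most summits, and in each other list the 4 members with the strongest summits and up to 2 members with none. Alternatives varied the distance, the peak set, the promoter window, the assignment of summits to genes, the motif windows and the replicates used. Leaving out a replicate meant keeping the IDR-thresholded peaks with a summit within 100 bp among the 11195 strongest of both other replicates, which left 8729, 9037 and 8450 peaks without replicates 1, 2 and 3. These sets are smaller parts of the IDR-thresholded list and keep its summits and signal, which came from replicates 2 and 3. They therefore show the effect of keeping recurrent peaks, and do not remove a replicate from the calls. For replicate agreement and Spearman's rho, the pairs with that replicate were left out instead. The tests of promoter share, replicate agreement, gene lists, motifs, 6-mers and signal ranks were first tested on simulated data; the binomial test and the tests chosen later were not. In 100 simulations each, with no preference put in, the promoter test gave p under 0.05 in 4%, the test of gene lists in 3% (Fisher's exact test without length matching in 9%) and the test of signal ranks in 4%. Simulated summits, bound genes and signals were drawn independently, whereas real summits cluster, so these rates do not cover clustering. Simulated binding also rose less with gene length than real binding did, and the simulated lists favoured long genes. The 3% and 9% are therefore not the rates of these tests for the real lists. A list of 17 genes of which 90% were made bound was called in 100% of 100 simulations. In 1 draw, 2 sets of windows moved away from the summits were compared with each other, and no motif and no 6-mer passed the threshold. These windows were not checked for other summits. Both sets were background, so the draw does not cover a difference in class of sequence. All 111 planted copies of the ecdysone response element were found, which shows only that the search finds exact matches. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1.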

Results

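USP occupancy was mapped in 3 biological replicates of whole wandering larvae, the stage at which the ecdysone pulse that ends larval life is underway. The IDR-thresholded list held 11195 peaks with a median width of 642 bp, and its intervals covered 6.15 Mb, or 4.59% of the 6 chromosome arms. The widest interval spanned 16229 bp and lay at Eip75B. The deposited signal, the authors' score per peak, had a median of 746 and ran from 365 to 47801. Values given as mean ± SD are over the 3 replicates' own lists (n = 3), and read depth was unknown from the files.

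The first comparison asked how far the replicates shared their sites. The strongest peak of all 3 replicates was the same site, on 2L at 15911773 inside beat-Ib, and the sites at vri and Eip74EF were among the first 4 peaks of each replicate. Replicates 1 and 2 shared 77.1% of their 11195 strongest summits within 100 bp, replicates 1 and 3 shared 82.3%, and replicates 2 and 3 shared 79.6%. The mean was 79.7% ± 2.62 (SD over 3 pairs), against 1.70% for rotated summits, and none of 1000 rotations exceeded 2.05%. The one-sided permutation p was 0.000999, the smallest that 1000 rotations can give. Spearman's rho of the signal of shared summits was 0.867 ± 0.0312 (SD over 3 pairs), a correlation across peaks, which are not independent. Replicate 1, which had no part in the IDR-thresholded list, held 87.4% of its summits among its own 11195 strongest and 97.1% in its full list. All 3 replicates held 7975 of the 11195 summits (71.2%) among their strongest.

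The design of the study, with the ecdysone receptor's partner tagged at the end of larval life, raises the question whether genes of the ecdysone response were occupied. All 17 regulators of that response had at least 1 summit, in the IDR-thresholded list and in each replicate's own list. The strongest belonged to vri, a bZIP repressor, with 20 summits (20.3 ± 0.577, n = 3) and its highest one in an intron on 2L at 5293125, rank 3 of 11195. Eip74EF, an early ETS-domain gene, followed with rank 4 in an intron on 3L at 17611950 and 31 summits (30.0 ± 2.00, n = 3). Eip75B, which encodes the nuclear receptor E75, had 82 summits (82.0 ± 1.00, n = 3), 1 of them upstream of its body on 3L from 17950953 to 18064696, more than any other protein-coding gene, with rank 10 at a promoter at 17971378. The broad-complex gene br ranked 13 with a summit on X at 1618246, which lies 91 bp from a TSS of the overlapping gene Mur2B, and Hr4 ranked 14 with an intronic summit on X at 1951623.

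Among the other regulators, the Krüppel-like gene Kr-h1 had 12 summits, the strongest at rank 23. EcR itself, on 2R from 6087873 to 6169087, had 32 summits (35.3 ± 5.86, n = 3), the strongest in an intron at rank 34. The receptor genes Eip78C, Hr39 and Hr3 had 17, 5 and 11 summits with best ranks of 46, 78 and 93, and the ABC transporter gene E23 had 8 with a best rank of 90. Blimp-1 reached rank 192 and Eip93F rank 483. The zinc finger gene crol reached rank 866, and ftz-f1, the competence factor that follows the pulse, reached rank 2114. The gene usp had 2 summits with a best rank of 1149 at its promoter, and Hr38 had 2 with a best rank of 6051. The labels do not say whether the tagged usp is an added copy, so the summits at usp are uncertain. Length-matched random lists had 10.1 bound genes of 17 on average, and the two-sided permutation p over 100000 lists was 0.00032 (adjusted p = 0.00168 over 21 lists).

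**Figure D1:**
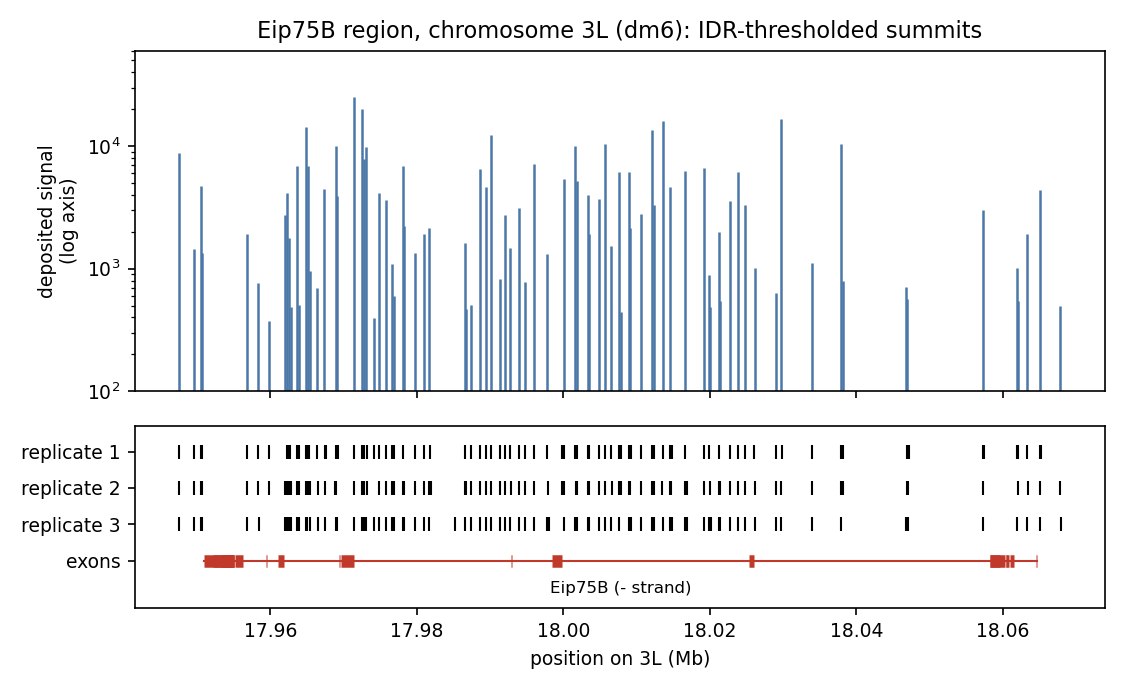
Eip75B on chromosome 3L, in Mb on dm6. The upper panel gives the deposited signal of each IDR-thresholded summit on a log axis; ticks in the lower panel mark the 11195 strongest summits of each replicate that fall here, over the exons. Of the 82 summits assigned to the gene, 81 lie in its body and 1 lies upstream; the replicates gave 82, 83 and 81 by the same rule.

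Of 19 ecdysone-induced effector genes 12 were bound, against 6.64 in length-matched lists (adjusted permutation p = 0.0471). Hsp27, a small heat shock gene long used to study the ecdysone response element, had its strongest summit at 9383521 on 3L at rank 225, and ImpE3, ImpL2 and ImpE2 had best ranks of 646, 799 and 1124. The late genes Eig71Ea and Eig71Eb had no summit. This call depended on Eip71CD and Eip55E, found under their newer symbols MsrA and Cth. With the fixed symbols alone 10 of 17 were bound and the adjusted p was 0.139, and with replicate 1 alone 10 of 19 were bound and the adjusted permutation p was 0.29. It was also lost with 5000 bp upstream (adjusted permutation p = 0.227) and in smaller sets: 10 of 19 were bound (52.6%) by the 9037 peaks also strong in replicates 1 and 3, against 31.4%, and by the 8450 also strong in replicates 1 and 2, against 29.3% (adjusted permutation p = 0.153 and 0.118).

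Genes of cell death and autophagy, the processes that remove larval tissues, were bound in 16 of 18 cases against an expected 7.93 (adjusted permutation p = 0.00084), with 15 ± 1 bound per replicate (n = 3). The apoptosome gene Dark ranked 127 and the effector caspase gene Drice ranked 195, both with promoter summits found in all 3 replicates. The autophagy kinase gene Atg1 and Atg17 had intronic summits at ranks 497 and 620. The death genes grim and skl had no summit. The call was lost with the 8450 peaks also strong in replicates 1 and 2, where 12 of 18 were bound, 66.7% against 37.6% (adjusted permutation p = 0.0817). Among coregulators of the receptor, 14 of 17 genes were bound against 8.70 (adjusted permutation p = 0.0471). The coactivator gene tai led with 24 summits and a best rank of 67, followed by the corepressor gene Smr at 892, Sin3A at 944 and the remodelling ATPase gene brm at 1909, while HDAC3 and rig had none. The coregulator call was lost with replicate 1 alone, where 12 were bound (adjusted permutation p = 0.298). In each of the 3 smaller sets of peaks also strong in 2 of the replicates 11 were bound (64.7%), against 45.1% to 46.9% (adjusted permutation p = 0.271 to 0.304). With the fixed symbols the count was the same and only the adjustment over the other lists moved the p (adjusted permutation p = 0.0557). The call was lost as well with summits within 500 bp of a TSS (0.244), with 5000 bp upstream (0.227), with the nearest TSS (0.43) and with the 5597 strongest peaks (0.409).

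Genes for cytoplasmic ribosomal proteins were bound in 59 of 85 cases (69.4%; 58.3 ± 0.577 per replicate, n = 3) against 25.8% in length-matched lists. The adjusted permutation p was 0.00021, from the smallest p that 100000 lists can give (2e-05). RpS19b stood at rank 81, RpS28a at 855, RpL26 at 1678 and RpL19 at 2425, and RpL10 and RpL15 had none. Among the 5597 strongest peaks 24 of the 85 genes were bound, 28.2% against 13.1%. Odorant and gustatory receptor genes lay at the other extreme, with 3 of 119 bound (2.52%; 3 in each replicate) against 29.1%, again at the smallest p (adjusted permutation p = 0.00021). These were Or67a at rank 854, Gr97a at 8148 and Gr63a at 8550, whereas Gr10a and Gr10b had no summit.

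Of the 21 lists, 6 passed an adjusted permutation p of 0.05, 5 above and 1 below expectation. Expectation took account of gene length only. Whether widely expressed genes are bound more often whatever their function was not tested, so these calls cannot be told apart from that. Genes of the muscle list, not all of them structural, were bound in 3 of 16 cases (Mef2, Tm1 and TpnC73F) against 7.79 (adjusted permutation p = 0.0675). Myosin heavy chain (Mhc) and Act57B had no summit. Heat shock genes were bound in 10 of 16 cases against 5.23 (adjusted permutation p = 0.0675): Hsp26 reached rank 366, Hsp68 743 and Hsp67Ba 847, and Hsp70Aa and Hsp70Ab had none. Testis-specific genes were bound in 2 of 25 cases against 6.58 (adjusted permutation p = 0.0941), namely Mst87F and topi, while aly and can had no summit. Neuronal genes were bound in 4 of 14 cases against 8.17 (adjusted permutation p = 0.0965), with Syx1A at rank 634 and elav at 1466 and no summit at brp or para. Some of these lists passed under other settings. Heat shock genes did so with the nearest TSS (adjusted permutation p = 0.00658), the 5597 strongest peaks (0.00514) and the 8450 peaks also strong in replicates 1 and 2 (0.018). Muscle genes did so with 5000 bp upstream (adjusted permutation p = 0.0155), neuronal genes with replicate 1 alone (0.0456) and testis-specific genes without length matching (Fisher's exact test, 0.0095). That unmatched test gave p under 0.05 in 9% of simulations with binding by length only, and the matched test in 3%. Binding depended less on length there than in these data, so 9% is not its rate for the testis-specific list.

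Genes of ecdysone synthesis and transport did not stand apart, with 6 of 18 bound against 7.80 (adjusted permutation p = 0.691). The importer gene Oatp74D reached rank 808, sro 1819, mld 2187 and shd, whose enzyme makes 20-hydroxyecdysone, 2460, while spo and sad had no summit. Juvenile hormone genes were bound in 9 of 13 cases against 5.38 (adjusted permutation p = 0.138), led by Kr-h1, the receptor gene gce at 816, Jheh1 at 1824 and Fpps, with none at Jhe or jhamt. Without length matching they passed (Fisher's exact test, adjusted p = 0.0468). That test gave p under 0.05 in 9% of simulations with binding by length only, which is not its rate for this list. Other nuclear receptor genes were bound in 6 of 12 cases against 5.79 (adjusted permutation p = 1), with Hnf4 at rank 181, svp at 2011, Hr78 at 2722 and knrl at 4067 and none at kni or tll.

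Larval fat body genes were bound in 10 of 15 cases against 7.02 (adjusted permutation p = 0.324). The list counted mid as unbound, a symbol that belongs to midline in this annotation and not to a fat body gene. The lipase gene bmm ranked 208, Lpin 700, the lipid droplet gene Lsd-2 842 and the GATA factor gene srp 920, and Lsp1alpha and apolpp had none. With the nearest TSS 12 of 15 were bound (adjusted permutation p = 0.0107). Genes of insulin and growth were bound in 9 of 19 cases against 8.26 (adjusted permutation p = 1). The insulin receptor gene InR had 16 summits with a best rank of 36, Akt reached 326, foxo 349 and ImpL2 799, while Ilp2 and chico had none. Cuticle and tanning genes were bound in 10 of 20 cases against 7.39 (adjusted permutation p = 0.487), with verm at rank 1075, Cht10 at 1516, the chitin synthase gene kkv at 2707 and Cht2 at 2834, and none at Edg84A or Edg91.

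Digestive genes were bound in 7 of 15 cases against 4.86 (adjusted permutation p = 0.494), with the proton pump genes Vha16-1 and Vha100-2 at ranks 653 and 1241, mex1 at 2417 and GATAe at 3606, and none at Amy-d or betaTry. Hemocyte genes were bound in 4 of 13 cases against 6.10 (adjusted permutation p = 0.495): ush at rank 52 with 23 summits, Hml at 1120, lz at 8002 and crq at 8413, with none at PPO1 or He. Glue genes of the salivary gland were bound in 2 of 10 cases against 1.68 (adjusted permutation p = 1), Sgs1 at rank 5492 and Sgs4 at 6300, and not at Sgs3 or Sgs7. Hox genes were bound in 4 of 8 cases against 4.81 (adjusted permutation p = 0.995), Antp at 5299, Scr at 5547, abd-A at 6918 and Ubx at 9717, and not at Dfd or pb. Circadian genes were bound in 6 of 10 cases against 5.40 (adjusted permutation p = 1), with vri, the kinase gene sgg at rank 25, cwo at 486 and Pdp1 at 2748, and none at per or Clk. In the whole annotation, 4990 of 13945 protein-coding genes (35.8%) were bound, and the replicates' own lists gave 5003, 4719 and 5145 (SD 217, n = 3). With the 5597 strongest peaks 3056 were bound.

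**Figure D2:**
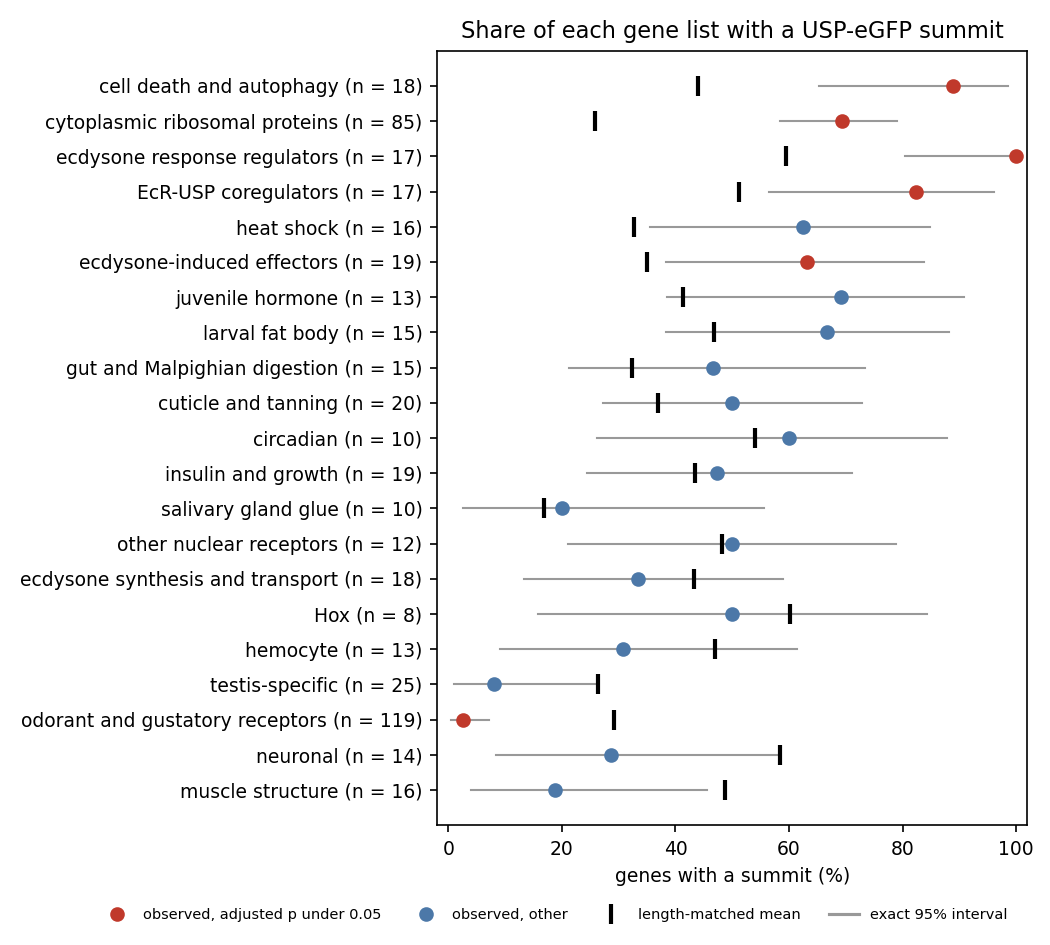
Share of genes with a summit (%) in each of 21 gene lists, with exact 95% intervals over genes and the mean of length-matched random lists as a black tick. Red points passed an adjusted p of 0.05; ecdysone response regulators stood at 100% against 59.5%, and odorant and gustatory receptors at 2.52% against 29.1%.

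Peaks of highest signal were described next. The first lay on 2L from 15910362 to 15914262 inside beat-Ib and the noncoding gene lncRNA:CR44867, with its summit 5115 bp from the nearest protein-coding TSS, that of CG13244. One interval on 2L from 2196114 to 2204002, which overlapped COX7AL2, held the peaks ranked 2, 8 and 15. The peak ranked 5 was intergenic on 3L at 3246573, 1442 bp from the TSS of CG43389, and that ranked 6 was intronic in atos on 2R at 11637537. Peaks 7 and 12 lay on 2L at 12014021 and 12012173, with Rh5 as the nearest protein-coding gene. Peak 9 was intergenic on 3L at 16195434, 2434 bp from the TSS of CG33687, and peak 11 was intronic in mam, the Notch coactivator gene, on 2R at 14000871. All 15 were found within 100 bp in each replicate's strongest 11195, and their ranks there ran from 1 to 17.

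Behind Eip75B, the genes with most summits were CG46467 and Glut4EF, which overlap on 3R and share 36 summits, and bun, a TSC22-family gene, with 36 (36.3 ± 2.08, n = 3). The zinc finger gene shn had 35, jing 34, EcR 32, Eip74EF 31, Mur2B 31 and sbb 30. The median gene of the same length class had 2 summits.

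Position in the genome was compared next with rotated summits. Promoters, within 500 bp of a TSS, held 4820 of the summits (43.1%; 43.1% ± 0.934, n = 3), and make up 13.5% of the genome. Introns held 42.0% of summits and 39.5% of the genome. Intergenic sequence held 9.72% of summits and 27.2% of the genome, coding sequence 1.75% and 13.7%, and 3′ UTRs 1.45% and 4.43%. The 5′ UTRs held 1.21% against 0.779%. Promoter, 5′ UTR, coding, 3′ UTR and intergenic shares differed from those of rotated summits at the smallest two-sided permutation p of 1000 rotations, 0.002 (adjusted p = 0.0028). The intron share had an adjusted permutation p of 0.0186, and noncoding exons, at 0.849% against 0.82%, had an adjusted p of 0.767.

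**Figure D3:**
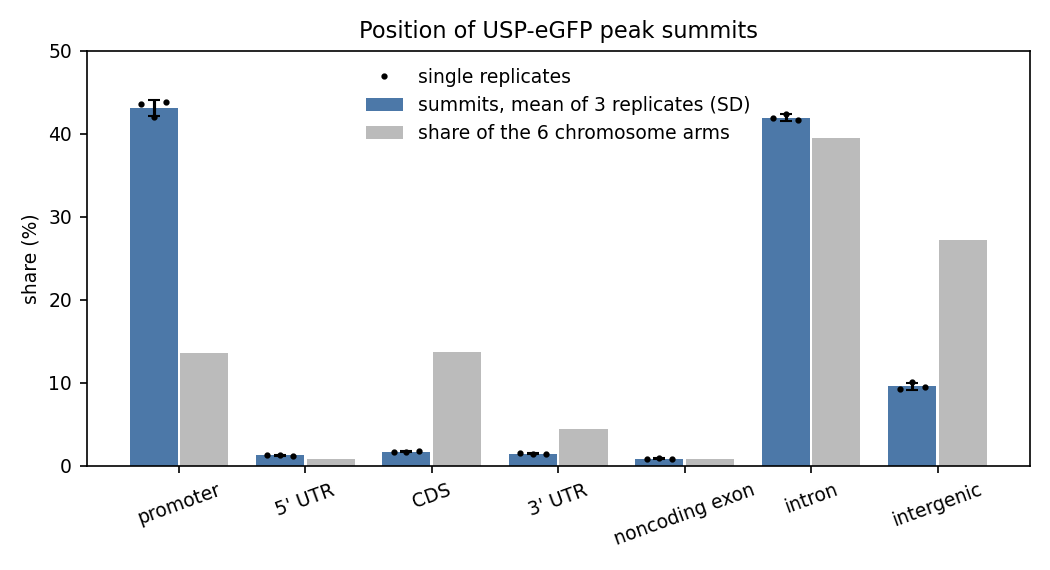
Share (%) of summits in each class of sequence, as the mean of the 3 replicates' strongest 11195 peaks with SD bars and single replicates as points, beside the share of the 6 chromosome arms in grey. Promoters held 43.1% of summits and 13.5% of the genome, while coding sequence held 1.69% and 13.7%.

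Strong sites lay slightly more often away from promoters. The median signal was 725 at promoter summits and 770 elsewhere, a median rank percentile of 48.5 against 51.4, and the difference was -2.93 percentile points (-3.46 ± 0.886 in the replicates, n = 3). It was -7.01 among the 5597 strongest peaks and -1.92 with promoters of 1000 bp. The two-sided permutation p was 0.00202, with peaks treated as independent. With a single summit per interval the difference was -3.13 (permutation p = 0.0033). Of the 100 strongest peaks 30% lay at promoters, 48% in introns and 17% in intergenic sequence. Among these 100 peaks, 34 were assigned to the 17 ecdysone response regulators, which held 302 summits in all (2.7%).

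The sequence under the summits was searched for the ecdysone response element in its palindromic form, a pair of hexamers facing each other across a single base (EcRE IR1, RGKTCANTGAMCY). A match lay within 100 bp of 50 summits (0.447%, exact 95% interval 0.332 to 0.588) and in 7 shifted windows (0.0625%), a ratio of 7.14. The exact McNemar p was 4.24e-09 (adjusted p = 2.12e-08), and none of 20 reordered consensus sequences had as high a ratio. The ratio rested on few shifted windows: another draw of their sides gave 0.0983%, a shift of 500 bp gave 0.0268%, and among the 8450 peaks also strong in replicates 1 and 2 the shares were 0.521% and 0.118%. With 200 bp on each side they were 0.527% and 0.17%, with a single summit per interval 0.494% and 0.112%, and with 1 mismatch allowed 3.74% and 0.697%. Each replicate's own list gave 0.441% ± 0.00516 (n = 3). The strongest peak with a match was at the promoter of bip1 on 3L, rank 72, where the site AGTTCAATGACCT ran from 8057617 to 8057629. An intron of br held AGTTCAATGACCC on X from 1577193 to 1577205 in the peak ranked 257, and an intron of Hr4 held AGTTCACTGAACT on X from 1949625 to 1949637 in the peak ranked 5698. The caspase gene Dronc had AGGTCATTGACCC in an intron on 3L from 9969384 to 9969396. The genes bip1 and Dronc were singled out after their values were seen.

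Of the 20 motifs, 8 were more frequent at summits and 1 less frequent at an adjusted exact p of 0.05. With summits outside promoters only, 7 were more frequent, and EcRE IR1 stood at 0.612% against 0.0627% (exact McNemar p = 3.11e-08). Shifted windows were not matched for class of sequence in either setting. GAGAGAG, bound by GAGA factor, stood at 9.22% against 3.96% (adjusted exact p = 9.48e-58). The DNA replication-related element TATCGATA (DRE) stood at 1.62% against 0.545% (adjusted exact p = 5.44e-14), and CGATAG, shared by Dref and BEAF, at 6.89% against 4.63% (adjusted p = 3.05e-12). The GATA site AGATAAG stood at 4.42% against 3.08% (adjusted exact p = 6.54e-07) and the AP-1 site TGASTCA at 3.43% against 2.32% (adjusted p = 2.31e-06). The direct repeat with a spacer of 4 bases (DR4) was found at 0.268% against 0.0983% (adjusted exact p = 0.0108), with 1 of 20 reordered sequences as high. The initiator TCAGTTY was found at 8.79% against 7.76% (adjusted exact p = 0.0123), with 3 of 20 as high. The Zelda site CAGGTAG was lower, at 1.06% against 1.54% (adjusted exact p = 0.00555), a ratio of 0.692, with 3 of 20 reordered sequences lower and their median ratio at 0.866.

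The other motifs did not pass. The single hexamer AGGTCA stood at 6.24% against 5.61% (adjusted exact p = 0.0902). The direct repeats DR1, DR2, DR3 and DR5 each occurred in at most 10 windows at summits (adjusted exact p = 0.606, 0.911, 1 and 0.732). The sites of Ftz-f1 (1.31% against 1.14%, adjusted exact p = 0.416) and ROR receptors (0.67% against 0.822%, adjusted p = 0.355), the E-box CACGTG (3.06% against 2.7%, adjusted p = 0.195), the Hnf4 site (0.339% against 0.322%, adjusted p = 1), the Broad-Z4 site (3 windows against 2, adjusted p = 1) and the TATA box (1.26% against 1.31%, adjusted p = 0.911) did not differ detectably.

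Of all 6-mers, counted with their reverse complements, 564 were more and 692 less frequent at summits at an adjusted exact McNemar p of 0.05. The 10 more frequent ones with the largest standardised difference were led by AGAGAG at 17.4% against 9.58%, CGATAA at 16.1% against 9.27% and CTTATC at 18.2% against 11.03%. The others were ACACAC (22.1% against 14.3%), CACACA (24.8% against 17.2%), CCCCCC (8.41% against 4.31%), GAGAGA, GAGAGC, AGAGCG and GAGCGA. Among the less frequent ones, AAGGAT stood at 3.17% against 7.62% and CCAGGA at 3.32% against 7.71%, both named after their values were seen. G and C made up 44.5% of summit windows and 42.9% of shifted windows. Class of sequence was not matched, so 6-mers can differ through position alone.

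The element was compared across peak strength. In 5 equal groups of 2239 peaks by signal, EcRE IR1 matched 1.07% of the strongest group (exact 95% interval 0.688 to 1.59) and 0.268% of the weakest (0.0984 to 0.582). The groups between them stood at 0.402%, 0.313% and 0.179%, from stronger to weaker. Peaks with a match had a mean rank percentile of 66.9 and those without one 49.9, a difference of 16.96 (16.2 ± 0.901 in the replicates, n = 3). The permutation p was 3e-05, two-sided, and rested on 50 peaks with a match.

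**Figure D4:**
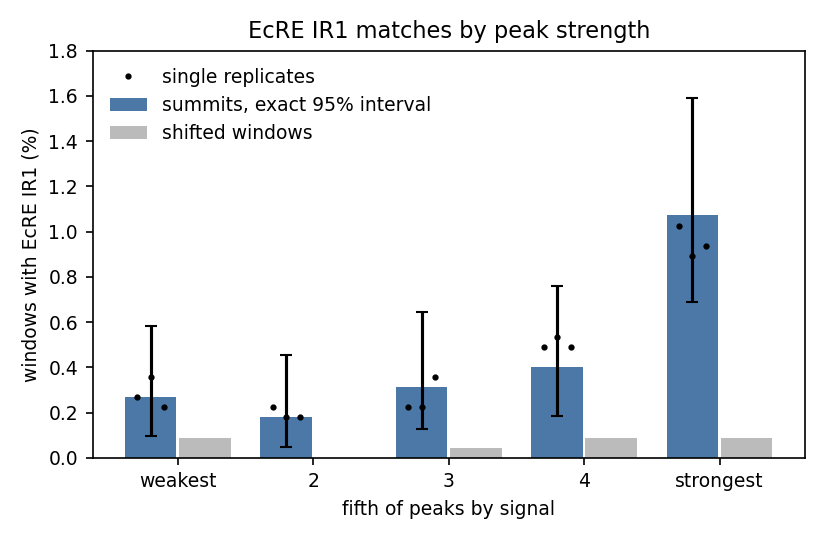
Share (%) of windows with EcRE IR1 in 5 equal groups of peaks by signal, with exact 95% intervals and single replicates as points; grey bars are the shifted windows of the same peaks. The strongest group stood at 1.07% and the weakest at 0.268%.

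Density along the chromosomes was compared last. X held 84.9 peaks per Mb and the arms 2L, 2R, 3L and 3R together 84.3, a ratio of 1.01 (0.989 ± 0.02 in the replicates, n = 3). The exact binomial p was 0.786, two-sided. Single arms ranged from 80.2 per Mb on 2L to 89.5 on 2R. Chromosome 4 held 10 peaks, or 7.42 per Mb, and 5 of its 80 protein-coding genes were bound: RpS3A, pan, zfh2, gw and Mpv17, all named after their values were seen. The ratio for X fell to 0.883 among the 5597 strongest peaks (exact binomial p = 0.000604). The binomial test treats summits as independent although they cluster, so its p can be too small. With a single summit per interval of the whole list the ratio was 0.987 (exact binomial p = 0.647). Arms differ in dosage in a pool of both sexes, and these ratios cannot be told apart from that.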

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

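Both results here concern summits left out of the IDR-thresholded list, and both were looked for after first results had been seen. The pooled list held 18805 summits below the IDR threshold, and 7499 of them (39.9%) had a summit within 100 bp in the full list of each of the 3 replicates. The pooled list was made from replicates 2 and 3, so recurrence in these was built in. In replicate 1, which was not a parent, 13284 of the 18805 (70.6%) had a summit within 100 bp, against 856 on average and at most 1163 in 200 rotations. Of these 7499 summits 29.8% lay at promoters, and 1106 protein-coding genes had such a summit and none above the threshold. They included Met, the juvenile hormone receptor gene, with its strongest on X at 11616497 (rank 11529 of the pooled list), the ecdysone synthesis genes dare on 2R at 11293194 (rank 12723) and dib on 3L at 4062199 (rank 20043), the collagen genes vkg (rank 11253) and Col4a1 (rank 11928), and chico (rank 12811). These genes were named after their values were seen. EcRE IR1 matched 15 of the 7499 windows (0.2%) and 9 shifted windows (exact McNemar p = 0.307). No explanation was tested.

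Replicate 1 had 575 summits among its 11195 strongest (5.14%) with no summit of the pooled list within 100 bp, a list to which it did not contribute. Of these, 77.04% lay inside an interval of the pooled list all the same, 52.5% lay at promoters, and 322 lay within 100 bp of a summit of replicate 2 or 3.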

How the results depend on the processing

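Of 114 alternatives over 12 results, 106 kept the result. For tests this meant the same direction and side of the threshold, and for counts a value within 1.5 times. For Spearman's rho it meant a value less than the SD over pairs, 0.0312, from the main one. Among the 106 were all those for replicate agreement, promoter share, promoter peak strength, and EcRE IR1 at summits and by strength. All those for the ecdysone response regulators, the number of motifs and the 6-mers were among them too. A rotation span limited to the pooled summits, a single summit per interval, replicate 1 on its own and the fixed symbols alone were chosen after seeing the data. The X-to-autosome ratio, 1.01 and not past the threshold, turned below 1 with a single summit per interval (0.987). It did so too in the 3 smaller sets of peaks also strong in 2 of the replicates (0.968 to 0.987). Among the 5597 strongest peaks it was 0.883, past the threshold. The cause was not tested, and arms differ in dosage in a pool of both sexes. Spearman's rho was 0.79 where summits up to 250 bp apart were paired, and 0.838 to 0.9001 with each replicate left out, which leaves 1 pair. The number of bound genes was 3056 with the 5597 strongest peaks, by construction fewer. The number of gene lists past the threshold ranged from 4 to 8, and was 4 in the sets of 9037 and 8450 peaks. Leaving a replicate out kept the IDR-thresholded peaks also strong in the others, 8729, 9037 and 8450 peaks. A call lost there cannot be put down to the replicate rather than to fewer peaks. A call kept there is no evidence that it holds without replicate 2 or 3, from which these summits and their signal were made. Replicate 1 had no part in that list to be removed. The peaks of highest signal in the pooled list were the IDR-thresholded peaks themselves, so 10 of the 106 could differ only through random draws and the number of permutations. Depth is not known from peak lists, and weak sites below the cap of 30000 cannot be seen.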

Other observations

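Tests of signal on X, of summits per ecdysone gene, of the distance of the element from the summit, of chromosome 4 gene content and of neighbours of ribosomal protein genes were chosen after the results were seen. Summits crowded at the ecdysone response regulators. These 17 genes had 17.8 summits per gene, median 11, against 3.62 in length-matched random lists (two-sided permutation p = 2e-05, the smallest that 100000 lists can give). Without Eip75B the mean was 13.8, above the highest mean of any random list, 12.7. Genes within a bin of length still differ in length, most of all in the bin of the longest genes. Part of the excess can therefore come from length. X-linked sites had lower signal than autosomal ones, with a mean rank percentile of 47.0 against 50.7. The difference was -3.63 (-2.83 ± 0.0611 in the replicates, n = 3). Its two-sided permutation p was 1e-05, the smallest that 100000 resamples can give, in a test that treats peaks as independent. In 5 equal groups by signal, the density on X relative to the autosome arms was 0.804 in the strongest and 1.16 in the weakest. Arms differ in dosage in a pool of both sexes, so lower signal on X cannot be told apart from weaker binding there. No explanation was tested.

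Matches to EcRE IR1 lay close to the summits, at a median distance of 19.5 bp against 47 bp for random placement in the windows (permutation p = 1e-05, one-sided, the smallest that 100000 draws can give; 50 matches). Yet only 0.447% of summits had an exact match. The 2 tests that follow were fixed before their values were computed, but matches with 1 mismatch and in wider windows had been counted by then. The first concerned a consensus that is too strict. With up to 2 mismatches 15.9% of summit windows and 6.3% of shifted windows matched, an excess of 9.65 percentage points. The excess was 0.384 points for exact matches and 3.05 with 1 mismatch, so it grew as the consensus was loosened. Most summits still had no match, but sites further from the consensus were not counted. The test thus cannot decide whether strictness is the whole account. The second concerned an element elsewhere in the peak. Exact matches in whole intervals exceeded those in shifted intervals by 0.46 percentage points (0.707% against 0.247%), so exact elements away from the summit were few as well. Inexact elements were not searched for in whole intervals, so the test cannot decide about them. Occupancy through other proteins or at open chromatin in general stays open, as no untagged control list was analysed here, and no biological explanation was tested.

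Binding at ribosomal protein genes may have come from neighbouring genes, but with each summit given only to the gene with the nearest TSS 58.8% of the 85 genes were bound (exact 95% interval 47.6 to 69.4), against 22.4% in length-matched lists; promoters shared with a neighbour stay open. Promoters with a DRE, a mark of many housekeeping genes, were bound in 47.5% of 1160 other genes (44.6 to 50.4), above the 38.2% of length-matched genes and below the lower bound for ribosomal protein genes, 58.5%, which argues against the DRE class as the whole account. A DRE lay at 24 of the 85 genes, 18 of them bound, and other kinds of housekeeping promoter were not tested. At the TSSs of ribosomal protein genes 55 summits lay at a median rank percentile of 39.1, against 48.6 at other promoters (permutation p = 0.127, two-sided), with a DRE in 12.7% against 3.19% and GAGAGAG in none against 9.72% of windows. Signal that follows transcription itself stays open, and no biological explanation was tested.

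Chromosome 4 had few peaks. Repeats could lower the number of mappable reads there, but 70.9% of 4 was unmasked in the reference against 80.05% of the other autosome arms, and per unmasked Mb its density was 0.0993 times theirs (exact 95% interval 0.0476 to 0.183). The number and length of its genes do not account for this either, since length-matched genes of the other arms would be bound in 54.1% of cases, against 6.25% of 80 genes (2.06 to 14.0). Whether any regions were removed before deposit is not given in the sources used here, so this stays open, and no biological explanation was tested.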
